A study of Pimephales promelas with 144 samples.

How the data were processed

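The data were scanner files of 144 Agilent arrays in the 8 x 15k format, each hybridised with Cy3-labelled RNA of 1 sample, and a table of processed values for the whole series. Per the file headers, spot brightness was extracted with Agilent Feature Extraction 11.0.1.1 (protocol GE1_1100_Jul11, array design 019597), and the processed intensity of a spot is its signal after background subtraction and spatial detrending within the array, with no scaling between arrays. The deposited files also hold the median intensity of each spot and of its local background, uncorrected, and flags for spots that are well above background, saturated or outlying. The authors' series table is in log2 units. Its 144 columns all have a median of 7.91 and the same distribution, which is what quantile normalization over all arrays gives. The ranks within a column follow the median spot intensity of the same array. Other steps behind that table are not given in the sources used here, and it served only as an alternative.

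Per the labels, 5 adult males and a mesh vessel of about 10 larvae shared each tank, brains were taken singly, and larvae were pooled in pairs of 2 survivors. Concentrations and deaths of each tank, the failed array checks and the replicate numbers are those of the labels. What the failed checks consisted of is not given in the sources used here, and whether the 0 µg/L groups held solvent carrier or water alone is not settled by the labels. Groups, tests, alternatives and the rule for named genes were fixed before the data were examined. Groups were formed by life stage, compound and nominal concentration. Of the 144 arrays, the 27 with at least 1 failed check were left out of the main comparisons, 13 in adults and 14 in larvae, and restored as an alternative. All columns used were matched to a sample, and 0 were left unmatched.

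Values were log2 of the processed intensity, floored at 1, minus the 75th percentile of each array. Spots flagged as outlying were set to missing, control spots were left out, and at most 2 saturated probes per array were kept. A probe was tested in a life stage when it was well above background on at least 50% of the arrays of at least 1 group, which left 14538 probes in adult brains and 14441 in larvae of 15208. On the arrays used, the median processed intensity of an array ranged from 84.2 to 329 in adults and from 95.0 to 358 in larvae.

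Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend), all 6 groups of a life stage in 1 fit, with the tank as a random block through duplicateCorrelation (statmod 1.5.0). The estimated correlation within a tank was 0.057 in adults, 0.044 in larvae and 0.055 in the fit over both life stages. P-values were two-sided and adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Log2 differences are exposed minus control, or bifenthrin minus cypermethrin experiment. The life stages were compared in 1 fit over 12 groups. Its block was the tank within a life stage, so adults and larvae of a shared tank were treated as separate units. Contrasts of the responses of the life stages were restricted to the 14228 probes kept in both. Larval deaths were compared by exact permutation over tanks. Tanks are separate units within an experiment, and each compound has a single experiment, so p-values measure the spread between tanks and arrays of that experiment.

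Classifiers were built in Python 3.11.15 with scikit-learn 1.9.0, numpy 2.4.6 and pandas 2.3.3. In each fold 1 tank was left out, the 50 probes with the largest absolute standardised difference were chosen among the training arrays, and an L2 logistic regression with C = 0.1 and balanced weights was fitted. The score of a tank is the mean over its arrays, and the area was computed within each experiment and averaged. Exposure was permuted over tanks within experiments 100 times with refitting. Transfer between compounds was tested over all 7056 pairs of relabellings of the 9 tanks of each experiment. Figures were drawn with matplotlib 3.10.9.

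The fit was tested on simulated data with 200 probes changed and no other difference. At 2-fold it recovered 52% to 62.5% of them over the 8 comparisons against control, and at 4-fold 81% to 92%. Over the 8 comparisons there were 64 false calls beside 932 recovered probes at 2-fold. When the same changes were added to the measured arrays, 46% to 60% of 2-fold changes were recovered in adults and 54.5% to 62.5% in larvae. At 1.5-fold the recovery was 17% to 30.5%, and at 4-fold 76.5% to 93.5%.

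The rule for named genes was to give, per comparison, up to 10 genes that rose and 10 that fell with all tank means apart. For probes without a gene name it allowed at most 2 identifiers that rose and 2 that fell. Of the 15208 probes, 0 matched any of 64593 reference genes of the organism by identifier, so the 30 gene lists and the cell type markers fixed beforehand were not tested and probes stand in for genes. Where no probe passed, the probe with the smallest p is given as not passing. The probes named in the comparisons between experiments are those of smallest p or of largest difference with all tank means apart, and they were chosen after the data were examined.

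Alternatives covered the background correction, the scaling, the filter on dim probes, slide and scan day as blocks, the tank block, arrays with failed checks, array weights, the replicate number as a block, fits within 1 experiment, the series table, each tank left out in turn, and for classifiers the number of probes, the method, the unit left out, slide centring and scaling. Within-day fits, the share of probes well above background as a covariate, normexp on the median intensity with an offset of 50 and fits without 1 larval or 1 adult array were added after seeing the data. So were the comparisons between the experiments and between the life stages at 0 µg/L.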

Results

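Transcripts were measured in fathead minnow (Pimephales promelas), a small freshwater fish used widely in toxicity testing, after 48 h of flow-through exposure to bifenthrin or cypermethrin. Both compounds are pyrethroid insecticides, which act on voltage-gated sodium channels of nerve cells. Cypermethrin carries an alpha-cyano group and bifenthrin does not. The series was made to build multigene classifiers of pyrethroid exposure and to compare dissected adult brains with whole larvae as their source. RNA came from brains of adult males on 73 arrays and from pairs of whole larvae on 71 arrays. The arrays fell into 12 groups: each life stage was held at nominal bifenthrin concentrations of 0, 0.148 and 0.593 µg/L and at nominal cypermethrin concentrations of 0, 0.25 and 1 µg/L. Each compound was run in an experiment of its own, with its own 0 µg/L tanks, and each group came from 3 tanks that adults and larvae shared. The 0 µg/L tanks carried the numbers 9, 12 and 17 in both experiments. They were treated as separate tanks, and a pairing by number was not tested.

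The labels counted failed array checks. The comparisons used the 117 arrays with 0 failed checks, 60 of adult brain and 57 of whole larva, with 8 to 12 arrays per group. On these arrays 87.7% ± 7.66 of the 15208 probes were well above background in adult brains (SD, n = 60, range 55.0% to 99.8%) and 88.9% ± 6.69 in larvae (SD, n = 57, range 65.5% to 99.5%). The number of arrays and tanks limits the precision of every value below. Over all arrays of the series, 2 of 18 adult tanks and 4 of 18 larval tanks held more arrays than fish or surviving larval pairs. Among the arrays with 0 failed checks, this held only for adult bifenthrin tank 8 and larval cypermethrin tank 5. The former had 6 arrays for 5 fish, the latter 5 arrays for at most 4 surviving pairs. Some arrays used thus shared a source, and the tank was kept as a block in the fit. The files pair probes with contig names and not with gene names, so probes are given by their identifiers and no gene group could be described.

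The exposures were well below nominal. Measured bifenthrin averaged 0.0252 ± 0.0013 µg/L at nominal 0.148 µg/L and 0.0718 ± 0.0129 µg/L at nominal 0.593 µg/L (SD, n = 3 tanks), which were 17.1% and 12.1% of nominal. Measured cypermethrin averaged 0.122 ± 0.016 µg/L at nominal 0.25 µg/L and 0.344 ± 0.016 µg/L at nominal 1 µg/L (SD, n = 3 tanks), or 48.8% and 34.4% of nominal. The control tanks were listed at 0 µg/L. None of the 90 adults died. Among larvae, 2 of 29 died in the bifenthrin controls, 0 of 30 at 0.148 µg/L and 2 of 30 at 0.593 µg/L.

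In the cypermethrin experiment 1 of 30 control larvae died, against 9 of 29 at 0.25 µg/L and 8 of 31 at 1 µg/L. The mean over tanks was 3.33% ± 5.77 in controls, 31.1% ± 1.92 at 0.25 µg/L and 25.2% ± 18.3 at 1 µg/L (SD, n = 3 tanks). The difference from control was 27.8 percentage points at 0.25 µg/L (exact permutation test over tanks, two-sided, p = 0.1) and 21.8 percentage points at 1 µg/L (exact permutation test, two-sided, p = 0.2). With 3 tanks against 3 the smallest p possible is 0.1, so these tests could not pass 0.05. For bifenthrin the corresponding exact p was 0.4 at 0.148 µg/L and 1 at 0.593 µg/L. The larval arrays hold only survivors.

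**Figure D1:**
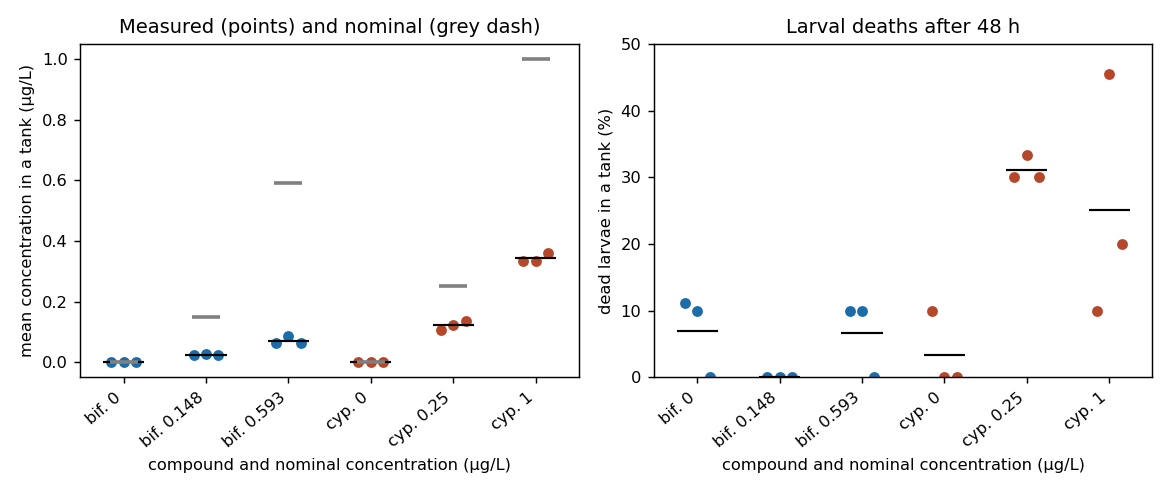
Left: mean measured concentration of each tank (points, µg/L) with the mean of 3 tanks (black line) and the nominal concentration (grey line). Right: dead larvae in each tank (points, percent) with the mean of 3 tanks (line). Every exposed tank lay below its nominal concentration, and the 3 tanks at 0.25 µg/L cypermethrin lay between 30% and 33.3% dead.

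The first question was whether exposed adult brains differed from the controls of their own experiment. Of the 14538 probes tested, 0 passed the threshold in any of the 4 comparisons (limma, adjusted p under 0.05). At unadjusted p under 0.05 limma counted 387 probes at 0.148 µg/L and 499 at 0.593 µg/L bifenthrin, and 413 at 0.25 µg/L and 470 at 1 µg/L cypermethrin. Each count was below the 726.9 that 5% of the tested probes would give. The median half-width of the 95% interval of a probe's log2 difference was 0.52, 0.49, 0.56 and 0.52 in the same order. The interval excluded a 2-fold change for 66.5%, 69.2%, 64.4% and 66.6% of probes.

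The probe with the smallest p in each comparison is given as not passing. UF_Ppr_AF_115877 measured 2.79 ± 0.72 (SE) higher on the log2 scale at 0.148 µg/L bifenthrin (adjusted p = 0.9997), with tank means of -3.97 ± 0.90 against -6.54 ± 0.47 in controls (SD, n = 3 tanks). It was well above background on 3 of 11 control arrays and 8 of 9 exposed arrays, and its difference at 0.593 µg/L was 2.06, so these sizes rest largely on dim control values. UF_Ppr_AF_109968 measured 1.14 ± 0.31 (SE) higher at 1 µg/L cypermethrin (adjusted p = 0.9996), with tank means of -0.20 ± 0.23 against -1.36 ± 0.05 (SD, n = 3 tanks). UF_Ppr_AF_108226 had a difference of -0.44 ± 0.11 (SE) at 0.593 µg/L bifenthrin (adjusted p = 0.995), and UF_Ppr_AF_103263 one of -0.97 ± 0.27 (SE) at 0.25 µg/L cypermethrin (adjusted p = 0.999). With normexp on the median intensity UF_Ppr_AF_115877 measured 0.86 higher and UF_Ppr_AF_103263 had a difference of -0.56. For all 4 probes every exposed tank mean lay beyond every control tank mean, an ordering that chance gives to 10% of probes with 3 tanks against 3. These probes were picked for their small p, which favours such an ordering, so it adds no support.

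The same question in whole larvae had the same outcome: limma passed 0 of 14441 probes in each of the 4 comparisons. At unadjusted p under 0.05 it counted 305 probes at 0.148 µg/L and 114 at 0.593 µg/L bifenthrin, and 233 at 0.25 µg/L and 439 at 1 µg/L cypermethrin, where 5% of the tested probes is 722.05. The median half-widths of the 95% intervals were 0.46, 0.48, 0.49 and 0.47 log2 units. A 2-fold change lay outside the interval for 75.5%, 76.2%, 72.8% and 74.3% of probes.

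The larval probes with the smallest p also did not pass. UF_Ppr_AF_115747 had a log2 difference of -2.66 ± 0.54 (SE) at 1 µg/L cypermethrin (adjusted p = 0.139), with tank means of -2.41 ± 1.58 against -0.18 ± 0.26 (SD, n = 3 tanks), and of -0.07 at 0.25 µg/L. Its adjusted p ranged from 0.024 to 0.99998 over 17 alternative settings and passed in 4 of them, and the difference was -3.05 within scan day 1 and -0.69 within day 2. Of the tanks at 1 µg/L, leaving out tank 5 gave -1.37 (adjusted p = 0.994), and leaving out tank 23 or 26 gave -3.06 and -3.17 and took it past the threshold. The 5 larval arrays of tank 5 came from at most 4 surviving pairs. UF_Ppr_AF_107333 had a difference of -0.68 ± 0.14 (SE) at 0.148 µg/L bifenthrin (adjusted p = 0.116) and of -0.09 at 0.593 µg/L. Its adjusted p ranged from 0.0122 to 0.9997 over 18 settings, passed in 2 of them, and passed without control tank 12, while without control tank 17 the difference was -0.49 (adjusted p = 0.912). UF_Ppr_AF_103074 had differences of -2.89 ± 0.74 (SE) at 0.593 µg/L bifenthrin (adjusted p = 0.99988) and -3.01 at 0.148 µg/L. It was well above background on 8 of 9 control arrays, 3 of 11 arrays at 0.148 µg/L and 4 of 9 at 0.593 µg/L, so these sizes rest largely on dim values. UF_Ppr_AF_107961 measured 1.96 ± 0.48 (SE) higher at 0.25 µg/L cypermethrin (adjusted p = 0.999904) and 0.93 higher at 1 µg/L. It was well above background on 5 of 8 control arrays, and with all arrays its difference at 0.25 µg/L was 0.94. With normexp on the median intensity the differences of UF_Ppr_AF_103074, UF_Ppr_AF_107961 and UF_Ppr_AF_115747 were -0.90, 0.58 and -1.68.

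Slide and scan day were tested as batches, since the arrays lay on 18 slides of 8 arrays scanned on 3 days. With the slide as a fixed block limma passed 0 probes in all 17 exposure contrasts, with 125 to 745 probes at unadjusted p under 0.05. Within scan day 1 the same contrasts gave 0 probes except 1 for the adult mean effect. Within scan day 2 they gave 0 in adults and in larvae 0 to 2, with 2 at each bifenthrin concentration. Day 3 held at most 3 arrays of a group, and a single slide held too few arrays for a fit of its own.

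A response shared by both compounds and concentrations was tested as the mean of the 4 exposed groups, each minus its own control. Limma passed 0 probes in adult brains, with 170 at unadjusted p under 0.05, and 0 in larvae, with 308. Averaging narrowed the median half-width of the 95% interval to 0.32 in adults and 0.30 in larvae. The interval excluded a 2-fold change for 86.6% and 92.5% of probes. The larval mean effect minus the adult one gave 0 of 14228 probes and 222 at unadjusted p under 0.05, so no difference between the life stages in the response was detectable. Tissue and life stage changed together in that contrast and cannot be told apart.

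The 2 compounds were compared by the difference of their effects, although neither their nominal nor their measured concentrations match and the experiments ran at different times. Limma passed 0 probes in adult brains (554 at unadjusted p under 0.05) and 0 in larvae (238). The median half-width of the 95% interval of the difference was 0.64 log2 units in adults and 0.59 in larvae, and the interval excluded a 2-fold difference for 56.5% and 62.5% of probes. For the other probes a 2-fold difference between the compounds was not excluded. The higher minus the lower concentration also gave 0 probes in each case. At unadjusted p under 0.05 there were 317 probes for bifenthrin and 1392 for cypermethrin in adults, and 235 and 362 in larvae. The 1392 probes were the only one of the 17 exposure counts above 5% of the probes tested, and the smallest adjusted p among them was 0.150. For cypermethrin in adults 6 probes passed with the slide as a random block in place of the tank and 1 with no block, and in larvae 1 passed with either and 1 with the scan day as a block or with all arrays.

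Log2 differences at the lower and higher concentration of a compound were correlated across probes, which are not independent replicates. Both concentrations share control arrays, which raises the correlation with no effect at all. In adults r was 0.62 for bifenthrin (covariance 0.073), against 0.47 and 0.051 for simulated unchanged groups, and 0.11 when the controls were split between the concentrations. For cypermethrin in adults r was 0.22 (covariance 0.032), against 0.50 and 0.067 simulated and -0.19 with split controls. In larvae the values were 0.66 for bifenthrin (covariance 0.052; simulated 0.50 and 0.043; split controls 0.05) and 0.44 for cypermethrin (covariance 0.037; simulated 0.51 and 0.048; split controls -0.05). All 4 observed values lay inside the simulated ranges, but these were wide. For r in adults they were 0.15 to 0.75 for bifenthrin and 0.03 to 0.83 for cypermethrin. In larvae they were 0.04 to 0.81 and 0.04 to 0.76. The simulation shuffled single arrays without regard to tank. It therefore cannot tell a modest shared effect of the concentrations from none.

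A further 3 correlations across probes used separate control arrays and formed 1 family. The bifenthrin effect against the cypermethrin effect gave r = -0.02 in adults (rho = -0.08, permutation p = 0.96, adjusted p = 0.96) and r = 0.03 in larvae (rho = -0.05, permutation p = 0.94, adjusted p = 0.96). The adult against the larval mean effect gave r = -0.24 (rho = -0.13, permutation p = 0.3, adjusted p = 0.9). Tests were two-sided over 100 relabellings of the tanks within an experiment. Adults and larvae shared tanks but were relabelled apart, so the p of the adult against the larval effect does not allow for shared tanks.

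**Figure D2:**
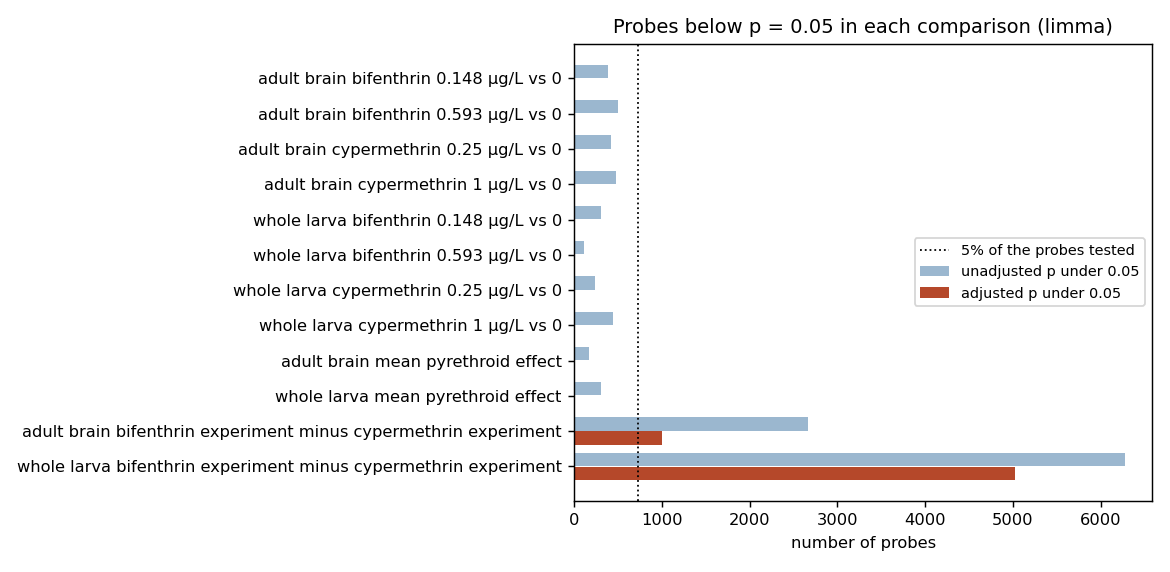
Number of probes below p = 0.05 in each limma comparison before adjustment (blue) and after adjustment (red), with 5% of the probes tested as a dotted line. The exposure comparisons shown have 114 to 499 probes before adjustment and 0 after it, while the differences between the experiments have 998 and 5028 after it.

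The series' classifiers were approached with a logistic regression on 50 probes, chosen again each time 1 whole tank was left out. The area under the receiver operating curve over tanks, where 1 means that every exposed tank scored above every control tank of its experiment, was 0.028 in adult brains and 0.222 in larvae. Permuting exposure over tanks gave a mean area of 0.324 in adults and 0.311 in larvae, so these means and not 0.5 are the reference. The one-sided permutation p was 1.0 in adults and 0.683 in larvae (100 permutations). The adult area lay below 0.083, the 5th percentile of the permuted areas, so control tanks scored above exposed ones more often than in most permutations. It changed with the setting and was 0 with all arrays, 0.028 with 200 probes and 0.111 with a support vector machine. With quantile normalization it was 0.139, as with single arrays left out. It was 0.25 with 10 probes and 0.306 with values centred on each slide (permutation p = 0.673 for each, one-sided). In adults 6 of 12 exposed tanks and 0 of 6 control tanks were classed correctly, and in larvae 10 of 12 and 0 of 6. The larval minus the adult area was 0.194 (permutation p = 0.366, two-sided).

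A classifier trained on one compound and tested on the other gave a mean area of 0.194 in adults (exact permutation, one-sided, p = 0.984) and 0.528 in larvae (exact permutation, one-sided, p = 0.465). The larval value fell to 0.222 when values were centred on each slide. Transfer between compounds was not tested on data with a known change. The exposure classifier with 1 tank left out was, in a single relabelling of the tanks. It reached an area of 1.0 in both life stages when the same 200 probes were raised 2-fold in every array labelled exposed. Asked which experiment a left-out tank came from, a question added after the data were examined, it classed 17 of 18 adult tanks correctly (area 0.975) and 18 of 18 larval tanks (area 1.0).

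**Figure D3:**
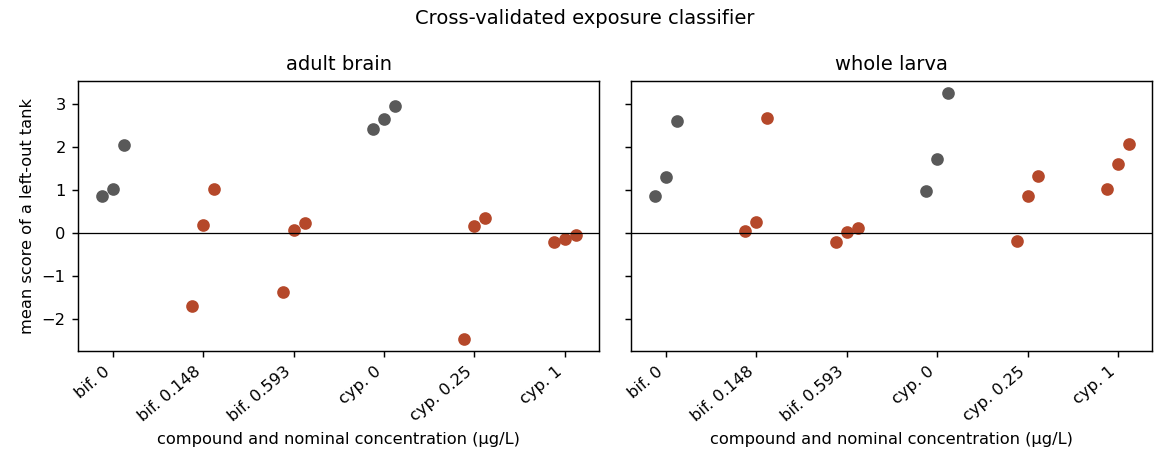
Mean score of each left-out tank in the exposure classifier (y axis, score on the log odds scale, above 0 is classed as exposed) for adult brains (left) and whole larvae (right), by compound and nominal concentration in µg/L. Points are tanks, grey for controls and red for exposed groups; all 12 control points lie above 0, that is on the exposed side.

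The following comparisons were added after the data were examined. The bifenthrin and cypermethrin experiments differed from each other in the mean over their 3 groups, 1 control and 2 exposed, and no exposed level was tested alone. In larvae, the 3 groups of the bifenthrin experiment differed from the 3 of the cypermethrin experiment at 5028 of 14441 probes (limma, adjusted p under 0.05), 3287 higher and 1741 lower in the bifenthrin experiment. In adult brains 998 of 14538 probes differed, 696 higher and 302 lower. Of all probes tested, 311 in larvae and 106 in adults differed by over 1 log2 unit, so most calls were below 2-fold. Across the 14228 probes kept in both life stages the adult and larval experiment differences correlated with r = -0.32 (rho = -0.34, not tested). The probe with the smallest p was UF_Ppr_AF_117594 in larvae, lower in the bifenthrin experiment by a log2 difference of -3.69 ± 0.36 (SE, adjusted p = 1.9e-10). In adults it was UF_Ppr_AF_109913, higher by 2.16 ± 0.25 (SE, adjusted p = 7.4e-08).

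With the slide as a block the larval count was 4853, and it was 1882 within scan day 1 and 2912 within day 2. The adult count was 739 with the slide as a block but 5 within day 1 and 25 within day 2, where 2076 and 1362 probes had an unadjusted p under 0.05. With the arrays of failed checks restored the counts were 2539 in larvae and 393 in adults, and with the slide as a random block the adult count was 1678.

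The 0 µg/L tanks of the experiments were then set against each other. Larval controls differed at 1439 of 14441 probes, 882 higher and 557 lower in the bifenthrin experiment. UF_Ppr_AF_112855 was 2.37 ± 0.74 (SE) higher there on the log2 scale (adjusted p = 0.0320), with tank means of 2.41 ± 0.84 against 0.16 ± 0.21. UF_Ppr_AF_102356 was 3.16 ± 0.92 (SE) higher (adjusted p = 0.0218), but was well above background on 4 of 8 arrays of the cypermethrin controls, so its size rests partly on dim values. UF_Ppr_AF_110144 was lower by -3.70 ± 0.76 (SE, adjusted p = 0.00211), with tank means of -1.87 ± 1.25 against 1.66 ± 1.24, and UF_Ppr_AF_117289 was lower by -3.12 ± 0.92 (SE, adjusted p = 0.0237). Adult controls differed at 13 of 14538 probes, all higher in the bifenthrin experiment, among them UF_Ppr_AF_109913 by 2.22 ± 0.43 (SE, adjusted p = 0.0161) and UF_Ppr_AF_108455 by 1.97 ± 0.43 (SE, adjusted p = 0.0350). The latter was well above background on 2 of 9 arrays of the cypermethrin controls, so its size rests largely on dim values. Tank means are over n = 3 tanks with SD.

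The larval count of 1439 rested on few tanks. It was 74 without bifenthrin tank 12, 38 without cypermethrin tank 9, 4 within scan day 1, 1422 within day 2 and 1952 with the slide as a block. It was 104 with all arrays, 188 on tank means, 493 with normexp and 2290 with the slide as a random block. Its split was nearly even with quantile normalization, and with normexp more probes were lower than higher in the bifenthrin experiment. The adult count of 13 was 0 with the slide as a block and 0 within either day, with 1012, 838 and 363 probes at unadjusted p under 0.05 by limma. It was higher in other settings, with 138 for all arrays, 106 for the slide as a random block, 105 with array weights, 61 with no block and 35 without replicate 11 of the 0.593 µg/L bifenthrin group.

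Whole larvae differed from adult brains at 0 µg/L at 8229 of 14751 probes, 3691 higher and 4538 lower in larvae (limma, adjusted p under 0.05). Differences over 2 log2 units passed at 1220 probes, 945 of them higher in larvae and 275 higher in adult brains. The larva minus adult differences of the 2 experiments, which share no arrays, correlated across probes with r = 0.91. The count was 8147 with the slide as a block, 6705 within scan day 1 and 6494 within day 2.

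The difference between the experiments at 0 µg/L was itself different in the life stages. Larval minus adult, it passed at 934 of 14228 probes, 524 higher and 410 lower (limma, adjusted p under 0.05). The count was 1154 with the slide as a block, 0 within scan day 1 (1095 at unadjusted p under 0.05 by limma) and 138 within day 2. Leaving out 1 larval control tank, bifenthrin tank 12 or cypermethrin tank 9, gave 177 and 108, and leaving out adult bifenthrin tank 9 or adult cypermethrin tank 17 gave 459 and 521. With normexp and in the authors' table more of the probes were lower than higher.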

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

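Of the tests here, the slide block as a test of a hidden exposure response, the comparisons between the experiments and between the life stages at 0 µg/L, and the fits with a covariate or without 1 array were chosen after the data were examined.

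Dixon's test of the most distant value was applied to groups of 4 to 10 arrays, on the share of probes well above background in 7 groups and on the values of named probes in 11 cases. It set apart 1 array. Replicate 10 of the larval cypermethrin controls had 65.5% of its probes well above background, against a group mean of 88.4% ± 10.3 (SD, n = 8) and a highest value of 99.2%. Its distance to the nearest array was 0.574 of the group's range. At the 95% level of the test chance gives about 1 in 20 cases. The other 5 groups held more than 10 arrays and were not tested. In 1 of them, adult brains at 0.593 µg/L bifenthrin, replicate 11 had 55.0% of its probes well above background against 83.6% on the nearest array, a distance of 0.655 of the group's range, which is wider than that of the array above. In adults at 1 µg/L cypermethrin the distance of replicate 9 was 0.463. Without replicate 11 the exposure counts in adults stayed at 0 (limma, 189 to 1468 probes at unadjusted p under 0.05), and the count between the adult controls was 35 instead of 13.

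The larval and adult differences between the experiments at 0 µg/L differed from each other at 934 probes by the test of that difference (limma, adjusted p under 0.05). Without replicate 10 of the larval cypermethrin controls the count was 770. That count also rested on few tanks: it was 177 without larval bifenthrin tank 12, 108 without larval cypermethrin tank 9, 459 without adult bifenthrin tank 9 and 521 without adult cypermethrin tank 17.

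Larvae of the bifenthrin and cypermethrin experiments differed at 5028 probes in the mean over their 3 groups, and 3 technical explanations were tested. The difference at an exposed level alone was not tested, and at 0 µg/L it was 1439. The slide was argued against by a count of 4853 with the slide as a fixed block. The scaling between arrays was argued against by 4566 after quantile normalization, and the share of probes well above background on each array by 5105 with that share as a covariate. What stays open is everything that differed between the experiments, such as the batch of larvae, the handling before extraction or a labelling run, which cannot be told apart because each compound was run once, and no biological explanation was tested. Across 14228 probes the experiment difference of adults against that of larvae gave r = -0.32. This correlation was not tested, so it does not tell whether the life stages shifted alike.

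No exposure comparison passed a probe, and 3 reasons why a response could have been missed were tested. For slide variation, the largest count over the 8 comparisons against control was 0 with the slide as a fixed block. Over 17 contrasts that fit left 125 to 745 probes at unadjusted p under 0.05 (limma). With the slide as a random block in place of the tank the largest count over the 8 was 1, as with no block at all. Over the 17 contrasts the random slide block gave at most 6 probes, for the adult cypermethrin concentrations. Many probes hidden by slide variation were thus not seen, but not excluded. The correlation within a slide was 0.17 in adults and 0.13 in larvae, and recovery of added changes was not measured with the slide in the fit. For an array-wide level of signal, the largest count was 0 when the share of probes well above background was a covariate. Recovery of added changes was not measured with that covariate either. A response hidden by the level of signal was thus not seen, but not excluded. Too few arrays for 2-fold changes stayed undecided, since a median of 56.75% of 2-fold changes added to 200 probes was called, and 88.5% of 4-fold changes. The same rise was added to all 200 probes at once, and recovery with fewer changed probes was not measured. An absent or small response at these measured concentrations stays open as well, as does a response in few fish or at another time, neither of which was tested.

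Other splits of the tanks were counted for each comparison, with the tank correlation held at its fitted value and outlying spots kept, so real counts can differ from those above. Chance was argued against for the experiments in adults. There 1 of 100 splits, the real one, gave 993 probes past the threshold and the highest other gave 5. In larvae it was argued against too, with 1 of 100 splits as large (4935, highest other 2789, a split that kept 14 of 18 tanks on their real side). A share of 1 in 100 is the smallest that 100 splits can give, so chance was made unlikely and not ruled out. For larvae against adult brains at 0 µg/L, 1 of 100 was as large (8158, highest other 7298). Chance was not argued against for the mean pyrethroid effect, counted at unadjusted p under 0.05: 93 of 100 splits were as large in adults (200, highest other 3490) and 75 of 100 in larvae (295, highest other 1712). Nor was it for the difference between the compounds, with 43 of 100 in adults (544, highest other 3823) and 88 of 100 in larvae (233, highest other 2786), or for the larval minus adult mean effect, with 78 of 100 (311, highest other 2316).

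With 3 tanks against 3 there are 10 splits, too few for a share under 0.05. At unadjusted p under 0.05 in adults, 4 of 10 were as large at 0.148 µg/L (396, highest other 1245) and 9 of 10 at 0.593 µg/L bifenthrin (499, 1479). For cypermethrin 6 of 10 were as large at 0.25 µg/L (539, 2409) and 8 of 10 at 1 µg/L (464, 980). The higher minus the lower concentration gave 9 of 10 for bifenthrin (317, 4118) and 1 of 10 for cypermethrin (1595, 881). In larvae 7 of 10 were as large at 0.148 µg/L (294, 1435) and 10 of 10 at 0.593 µg/L bifenthrin (121, 1096), and 9 of 10 at either 0.25 µg/L (230, 1428) or 1 µg/L cypermethrin (411, 1768). The larval concentrations gave 9 of 10 for bifenthrin (233, 1206) and 10 of 10 for cypermethrin (273, 1979). Past the adjusted threshold, 1 of 10 splits was as large for the adult controls (13, highest other 1), the larval controls (1416, 15) and the larval minus adult difference between the experiments (913, 0). Several splits that mix the groups called many times more than the real one, among them 2005 probes past the adjusted threshold for the adult bifenthrin concentrations, 105 for the larval cypermethrin concentrations and 507 for the larval minus adult mean effect. Such counts may come from a structure of the samples other than exposure. Its source was not tested, and the slide was not in these fits.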

How the results depend on the processing

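The fits within 1 scan day, with the covariate, with normexp and without replicate 10 or 11, and every comparison between experiments or life stages, were chosen after the data were examined. Of 301 exposure counts recomputed, not counting fits without a tank or array, 283 were 0 and the other 18 were 1 to 6. All counts are by limma, and the cause was not tested for any that moved, beyond fewer arrays within a day and fewer units on tank means.

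Among exposure counts of 0, the adult cypermethrin concentration difference became 1 with no block and 6 with the slide as a random block, and the adult mean effect 1 on day 1. In larvae, 0.148 µg/L bifenthrin became 1 with no block, 1 with the slide random and 2 on day 2, where 0.593 µg/L gave 2 and the mean effect, the compound difference and the bifenthrin concentration difference gave 1 each. Cypermethrin at 1 µg/L became 1 with all arrays, with array weights, with no block and with the slide random. The cypermethrin concentration difference became 1 with all arrays, with no block, with scan day as a block and with the slide random. Leaving out each tank gave 0 to 1 for adult 0.593 µg/L bifenthrin (1 without tank 20), 0 to 1 for larval 0.148 µg/L bifenthrin (1 without tank 12), 0 to 1 for larval 1 µg/L cypermethrin (1 without tank 23 or 26) and 0 to 2 for the larval cypermethrin concentrations (2 without tank 23, 1 without tank 26). The other exposure counts without a tank stayed at 0.

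For UF_Ppr_AF_107333 the adjusted p was 0.0122 with the slide random, 0.0357 with no block and 0.0169 without tank 12 (0.0122 to 0.9997 over 18 settings). For UF_Ppr_AF_115747 it was 0.0240 with all arrays, 0.0434 with weights, 0.0385 with the slide random, 0.0386 with no block, and 0.0172 and 0.0256 without tanks 23 and 26, but 0.994 without tank 5, where the difference was -1.37 instead of -2.66 (0.024 to 0.99998 over 17 settings). Leaving out tanks aside, 6 values of named probes came to pass and 133 kept direction and side of the threshold, but sizes moved. Over these settings UF_Ppr_AF_115877 was 0.86 (normexp) to 2.82, UF_Ppr_AF_103074 -3.82 (day 2) to -0.90 (normexp), UF_Ppr_AF_107961 0.58 (normexp) to 2.28 (day 1), UF_Ppr_AF_103263 -1.30 (tank means) to -0.56 (normexp) and UF_Ppr_AF_115747 -3.05 (day 1) to -0.69 (day 2).

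The 13 probes of the adult controls became 138 with all arrays, 105 with array weights, 61 with no block, 106 with the slide random, 33 with normexp, 47 when every array had to be well above background, 3 with quantile normalization and 39 with the covariate. They became 0 on tank means, 0 with the slide fixed, and 0 on day 1 and day 2 (1022, 1012, 838 and 363 at unadjusted p under 0.05). Leaving out a tank or array gave 0 to 35: replicate 11 of 0.593 µg/L bifenthrin 35, bifenthrin tank 9 0 and tank 12 4, cypermethrin tank 9 7, tank 12 31 and tank 17 0 (635 and 726 at unadjusted p under 0.05 for the counts of 0).

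The 998 probes between adult experiments became 393 with all arrays, 442 on tank means, 5 on day 1, 25 on day 2, 650 with quantile normalization and 1678 with the slide random. Leaving out a tank gave 556 to 1262, with 581 without bifenthrin tank 14 and 648 and 556 without cypermethrin tanks 17 and 28. The 5028 larval probes became 2539 with all arrays, 1882 on day 1 and 2912 on day 2, and 4010 to 5316 without a tank.

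The 1439 probes of the larval controls became 104 with all arrays, 188 on tank means, 493 with normexp, 4 on day 1 and 2290 with the slide random. Leaving out a tank gave 38 to 1354, with 74 without bifenthrin tank 12 and 38 without cypermethrin tank 9, and leaving out replicate 10 gave 884. The 934 probes of the larval minus adult difference became 602 with at most 1 failed check, 453 on tank means, 517 with normexp, 0 on day 1 (1095 at unadjusted p under 0.05), 138 on day 2 and 1840 with the slide random. Leaving out a tank gave 108 to 1067: 459 and 521 without adult bifenthrin tank 9 and cypermethrin tank 17, 177 and 108 without larval bifenthrin tank 12 and cypermethrin tank 9. The 8229 probes between life stages stayed within 1.5 times.

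Scaling moved the split of higher and lower calls: 882 and 557 in the larval controls became 538 and 527 with quantile normalization, 207 and 286 with normexp and 566 and 574 in the authors' table. For the larval minus adult difference 524 and 410 became 232 and 285 with normexp and 410 and 494 in the authors' table.

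The larval area of 0.528 across compounds was 0.389 with 10 probes, 0.389 with all arrays and 0.222 with slide centring, and the larval exposure area of 0.222 was 0.556 when single arrays were left out, so that a tank had arrays on both sides. The 22 other areas did not cross 0.5, though the larval one across compounds was 0.5 with a support vector machine. The adult exposure area of 0.028 was 0 to 0.306. The one-sided permutation p of the exposure areas was 0.485 or more in every setting.

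Replicate numbers did not pair samples (mean r of same-numbered arrays -0.017 in adults, 0.011 in larvae). With the replicate block all 17 exposure counts were 0 (79 to 859 at unadjusted p under 0.05), and the experiment counts were 798 in adults and 4887 in larvae, with 17 and 1161 in controls. Normexp on the mean intensity was not run, as the files used here give the median, nor were gene list alternatives, since no probe had a gene name. Well above background were 55.0% to 99.8% of probes on an array, which limits dim probes.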

Other observations

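The tests on probes that switch between bright and dim were planned before their results were seen, and the 2 probes given as examples were chosen after.

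Some probes were bright on some arrays and not well above background on others, with a wide gap between. A probe was counted when it was dim on 20% to 80% of the arrays of a life stage and its median bright and dim values lay at least 3 log2 units apart. There were 476 such probes in adult brains and 194 in larvae of 15208, with 152 in both. The median gap was 3.62 log2 units in adults and 3.50 in larvae. UF_Ppr_AF_103241 had a gap of 9.29 and was dim on 18 of 60 adult and 9 of 57 larval arrays. UF_Ppr_AF_114276 had a gap of 9.66 in larvae and was dim on 13 of 57 larval and 30 of 60 adult arrays.

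A candidate explanation for these probes is a recessive variant carried by single fish that abolishes the signal. A larval array holds 2 larvae, so dim larval arrays would then be rarer, and the ratio of the log dim shares would lie between 1.5 and 2.5. The median ratio over the 476 probes chosen in adults was 0.901 (95% bootstrap interval 0.840 to 0.968), below that range. Of these probes, 208 were dim less often in larvae, as the variant would have it. Tissue differs with life stage, however, and can change the dim share of a probe by itself, so the ratio cannot decide on the variant. Of the 194 probes chosen in larvae, 162 were dim less often in adult brains, where the variant would make them dim more often. These probes were chosen by their larval dim share, so a lower share in adults can come from the choice alone. The slide stayed undecided: 15.97% of the adult probes and 4.64% of the larval ones had a permutation p under 0.05 for slide, where chance gives 5%.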
